A study of Mus musculus with 6 samples.

How the data were processed

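Gene expression was measured in 6 pools of mouse oocytes on 2-colour microarrays with 60-base probes. Each array carried 43451 spots, of which 1417 were controls and 42034 belonged to 42006 probes; 7 probes were spotted 5 times each. Per the labels' protocols, oocyte RNA was labelled with Cy3 after 2 rounds of linear amplification, and every array was co-hybridised with the same Cy5-labelled reference, a pool of RNA from 11 cultured mouse cell lines mixed 2 to 1 with embryonic stem cell RNA. The sample characteristics name embryonic stem cells at the embryo stage for all 6 arrays, while titles, descriptions and protocol name oocytes; the titles were followed. The dyes were never swapped, so a dye effect of a probe is part of every ratio and cancels only in differences between arrays.

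The scanner files were used as the starting point. Per the file headers, they were made with Agilent Feature Extraction version 9.5.1.1. They hold the intensity of each spot and its local background in each channel, on a linear scale and not normalised, together with processed intensity values that the authors' software had background-subtracted and dye-normalised by a linear and a lowess step. The deposited log ratio is the log10 of Cy5 over Cy3, per the file headers, and its sign was turned here so that a higher value means more oocyte RNA. Each scanner file already combines a bright and a dim reading, since its spots carry a mark where the dim reading was scaled up. The 4 arrays of the SN and NSN groups have 2 such files each and the 2 oocyte arrays have 1 each. The file with the larger total signal was used, and the other file served as an alternative; a rescan was never counted as a replicate. No spot of a probe was saturated on any array used, and at most 9 spots per array were left out because they were marked as uneven.

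The authors' processed table holds 25030 probes. Its scale is log10: per array, its values correlated with the log10 of the deposited Cy3 processed intensity with r between 0.9938 and 0.9977 over probes. Its column medians were 2.477 and 2.439 for oocyte, 2.574 and 2.563 for SN, and 2.546 and 2.567 for NSN. The departures of the table from the Cy3 values of the scanner files followed the Cy5 departures of each probe from its mean over arrays with r = -0.971, so the values are Cy3 levels adjusted by the reference channel. Higher values meant more Cy3 signal. How the 25030 probes were chosen, and the exact centring of each column, stay unknown. Per the labels, values under 2.0 were raised to 2.0 in the final analysis, but between 36.5 and 41.3 percent of the deposited values per array lie below 2, so that step was applied here before the table was used as an alternative.

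Spot intensity was background-corrected with the normexp method (offset 50) of limma 3.58.1 in R 4.3.3, and the log2 ratio of Cy3 over Cy5 was normalised within each array by loess, with control spots at weight 0. Spots of one probe were averaged. A probe was tested where Feature Extraction marked it well above background in Cy3 on at least 2 arrays of the fit. Differences were tested two-sided with limma's linear models and moderated variances, with Benjamini-Hochberg adjustment over the probes tested and an adjusted p under 0.05 as the threshold for a call. NSN against SN was fitted on the 4 arrays of these groups, which share a slide. SN against oocyte and NSN against oocyte were fitted on all 6 arrays. Where a probe was not well above background on any array of one group, only a bound on its difference exists there; a bound in folds depended on the setting, so the measured means and the range of the difference over the settings run are given instead.

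The files name every probe by its own array identifier and do not pair these identifiers with genes; 0 probes carried another name. The 20 gene lists and the genes chosen by name before the data were examined were therefore not used here, and no genome positions are given. The rule for named items, fixed before the data were examined, took the called items with the largest log2 differences in each direction whose arrays did not overlap between groups and which were well above background on every array of the higher group, filled by the smallest p where too few were called. Without gene names it was applied to probe identifiers and limited to 2 higher and 2 lower per comparison. Counts are therefore counts of probes, and several probes can belong to one gene. Pairs of probes that carry one sequence under different names served as a check: over 15 such pairs the NSN minus SN differences departed from each other by a median of 0.0562 on the log2 scale, and the SN minus oocyte differences by 0.0537.

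The fits were tested on simulated data made from the arrays' own means and spreads, with 200 probes changed by known amounts. For NSN against SN (28425 probes), 1 of 50 probes changed 2-fold was called, 26 of 50 changed 4-fold, 38 of 50 changed 8-fold and 44 of 50 changed 16-fold, with 2 unchanged probes called. For SN against oocyte (29030 probes) these counts were 12, 34, 40 and 48 of 50, with 2 unchanged probes called, and for NSN against oocyte (29030 probes) they were 12, 41, 45 and 49 of 50, with 7. Far more probes than the 200 simulated were called against oocyte in the real data (17914 for SN, 17625 for NSN). The simulated shares therefore do not carry over to those comparisons. The shares for NSN against SN depend on the 200 planted changes, which reached 16-fold, because the adjusted threshold depends on how many probes change. In the real data 59 probes were at least 4-fold lower in NSN without overlap, and 0 were called. The simulated shares are therefore not taken to hold for NSN against SN either. Alternatives covered the background offset, the deposited log ratio, median centring without loess, the Cy3 channel alone in 2 scalings, the other scan, the filter on dim probes, the authors' processed table, other variance models, a block for the replicate number or slide, the arrays in the fit, and each array left out in turn. Figures were drawn with matplotlib 3.10.9. With 2 arrays per group, the number of arrays limits the precision of every value.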

Results

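The study compared mouse antral oocytes, those of follicles that have formed a fluid-filled cavity, by the arrangement of their chromatin. In SN oocytes (surrounded nucleolus) a ring of condensed chromatin encloses the nucleolus, and in NSN oocytes (not surrounded nucleolus) the chromatin is dispersed and no ring is seen; both classes were told apart with a DNA dye. The series title names the arrest of embryos at the two-cell stage and the cytoplasmic lattices, fibrous structures that fill the oocyte cytoplasm. RNA was measured in 3 groups of 2 pools each. Both SN pools held 50 oocytes, the NSN pools held 41 and 44, and the remaining group, labelled only as oocyte, held 10 per pool. The protocol, given alike for all samples, speaks of antral oocytes, but the sample characteristics name embryonic stem cells, so what the oocyte group was beyond its title is not settled. The protocol mentions wild-type animals and a mutant of the maternal gene Mater, without saying which pools came from which. The labels do not say whether the 2 pools of a group came from separate animals, so the p-values measure the spread between these pools, which may be technical. All 4 SN and NSN arrays lay on slide 3, while the oocyte arrays lay on slides 1 and 2.

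Cy3 signal was higher on the SN and NSN arrays than on the oocyte arrays. The mean Cy3 intensity over probe spots was 5046 and 4719 in SN, 5004 and 5361 in NSN, and 2110 and 1417 in oocyte. Probes well above background in Cy3 numbered 29780 and 27261 in SN, 27168 and 27730 in NSN, and 23744 and 22011 in oocyte, out of 42006. In the Cy5 reference channel 28668 to 29984 probes per array were well above background. Across probes, the log ratios of the 2 arrays of a group correlated with r = 0.986 in SN, 0.9864 in NSN and 0.9863 in oocyte. Between SN and NSN arrays r lay between 0.977 and 0.985, and between oocyte arrays and the others between 0.7543 and 0.798. Probes are not independent replicates, and these values describe the arrays only.

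SN and NSN oocytes, the comparison the series was designed around, had closely similar profiles, with a tail of probes whose signal was lower in NSN. Among probes whose arrays did not overlap between the groups, 671 were at least 2-fold lower in NSN and 63 were at least 2-fold higher. The size of this imbalance depended on the processing: the counts were 1538 and 633 with the deposited log ratio, 1667 and 602 with Cy3 alone scaled to the 75th percentile, and 654 and 3 with Cy3 alone quantile-normalised, and with 1 array left out they ranged from 582 to 1000 and from 124 to 287. Non-overlap is easier to meet with 1 array left out, so those counts do not compare directly with 671 and 63. The 671 probes had a median difference of -1.35 on the log2 scale (2.55-fold), and 59 of them were at least 4-fold lower. Most were measured in both groups: 593 of the 671 were well above background on all 4 arrays. Counted by detection, 455 probes were well above background on both SN arrays and on neither NSN array, and 136 showed the reverse. Detection alone did not set the classes apart, since the same counts were 402 and 128 when replicate 1 of both groups was set against replicate 2, and 494 and 85 when the numbers were crossed. Across all 28430 tested probes the median difference was 0.03, with the first percentile at -1.44 and the ninety-ninth at 0.77.

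No probe passed the test between NSN and SN. limma called 0 of 28430 probes, with a smallest adjusted p of 0.112, and 3107 probes had an unadjusted p under 0.05, where 1422 are expected by chance. Groups of 2 against 2 did not overlap for 44.42 percent of the probes, where chance gives 33.3 percent. The count of 0 depended on the fit: with median centring in place of loess, 135 probes were called, all 135 lower in NSN, and with all 6 arrays in one fit 89 were called, 87 of them lower in NSN.

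**Figure D1:**
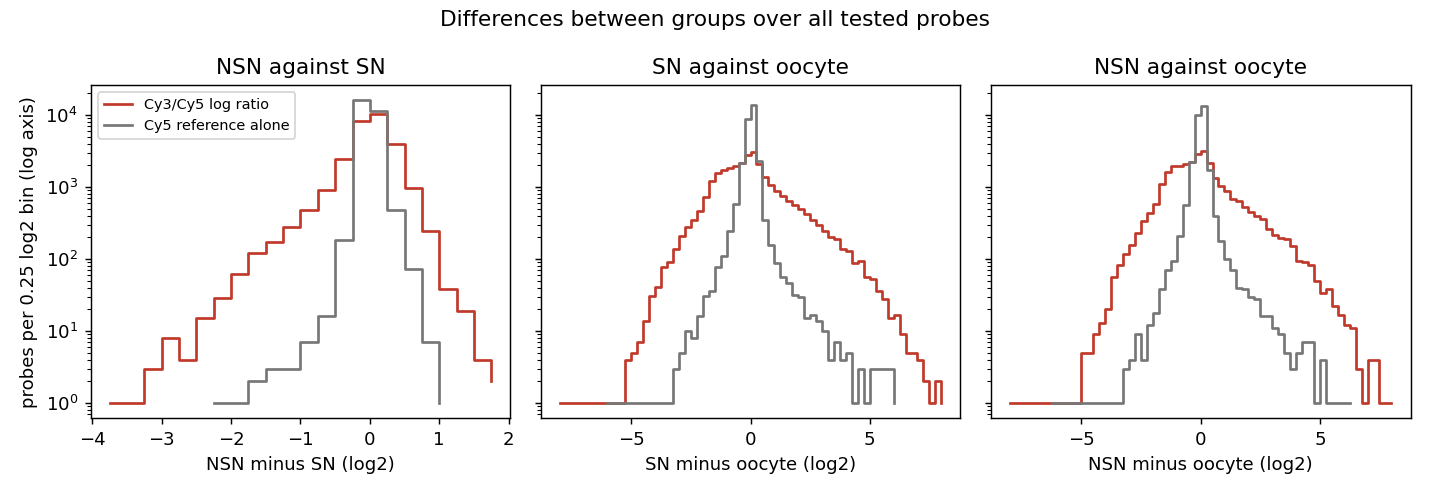
Number of probes (log axis) by the difference between groups in bins of 0.25 on the log2 scale, for the Cy3 over Cy5 ratio and for the Cy5 reference signal alone. In NSN against SN the ratio has a longer tail on the lower side, down to -3.64 against 1.91 on the higher side, and in both comparisons with oocyte the ratio spreads far more widely than the reference.

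Of the probes lower in NSN, Z00057348-1 (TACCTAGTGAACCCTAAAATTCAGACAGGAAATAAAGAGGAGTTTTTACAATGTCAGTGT) had the smallest p. Its log2 ratio was 4.56 ± 0.0072 (SD, n = 2) in SN and 1.525 ± 0.18 (SD, n = 2) in NSN, a difference of -3.03 with a 95% confidence interval from -3.42 to -2.64 (limma, adjusted p = 0.112). Its Cy5 signal was not well above background on any of the 4 arrays, so its ratio rests on the Cy3 channel. Probe Z00002490-1 (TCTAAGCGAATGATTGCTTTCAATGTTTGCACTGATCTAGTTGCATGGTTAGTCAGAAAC) measured 1.29 ± 0.079 in SN and -1.69 ± 0.18 in NSN, a difference of -2.98 (interval -3.38 to -2.58, limma adjusted p = 0.112). Neither probe was well above background on the oocyte arrays. On the higher side, Z00034805-1 (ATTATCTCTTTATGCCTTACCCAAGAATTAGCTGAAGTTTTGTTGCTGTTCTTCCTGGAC) measured 0.62 ± 0.077 in SN and 1.84 ± 0.0057 in NSN, a difference of 1.22 (interval 0.89 to 1.56, limma adjusted p = 0.129). Probe Z00070859-1 (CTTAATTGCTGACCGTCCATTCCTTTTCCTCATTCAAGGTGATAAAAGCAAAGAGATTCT) measured 1.85 ± 0.22 in SN and 3.45 ± 0.18 in NSN, a difference of 1.59 (interval 1.12 to 2.07, limma adjusted p = 0.137). Its Cy5 signal too was not well above background on any of the 4 arrays, and its difference was 0.62 with the deposited log ratio and 0.78 with the authors' processed values. Over all settings run the differences ranged from -3.21 to -1.84 for Z00057348-1, from -5.00 to -2.75 for Z00002490-1, from 0.66 to 1.88 for Z00034805-1 and from 0.62 to 1.84 for Z00070859-1. The 4 probes are given as values, since none passed the threshold. In each, the 2 groups were separated on all 4 arrays, which the rule for choosing them required. The files do not pair these identifiers with genes.

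The probes apart between NSN and SN differed in their level in the other samples. The 671 probes lower in NSN had a median log2 ratio of 0.14 in SN, -1.14 in NSN and -1.03 in the oocyte group. The NSN pools stood apart, with medians of -1.39 in replicate 1 and -0.904 in replicate 2. Of these probes, 60.4 and 54.1 percent were well above background in Cy3 on the oocyte arrays, against 80.4 and 75.7 percent of all tested probes. The 63 probes higher in NSN had a median of 0.66 in SN, 1.78 in NSN and 0.12 in oocyte. Both sets were chosen by their difference between SN and NSN, so their medians do not show which class the oocyte group resembles. The reference signal of the 63 probes was low, at a median of -3.74 on the log2 scale against the array's 75th percentile, and that of the 671 probes was -0.093.

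**Figure D2:**
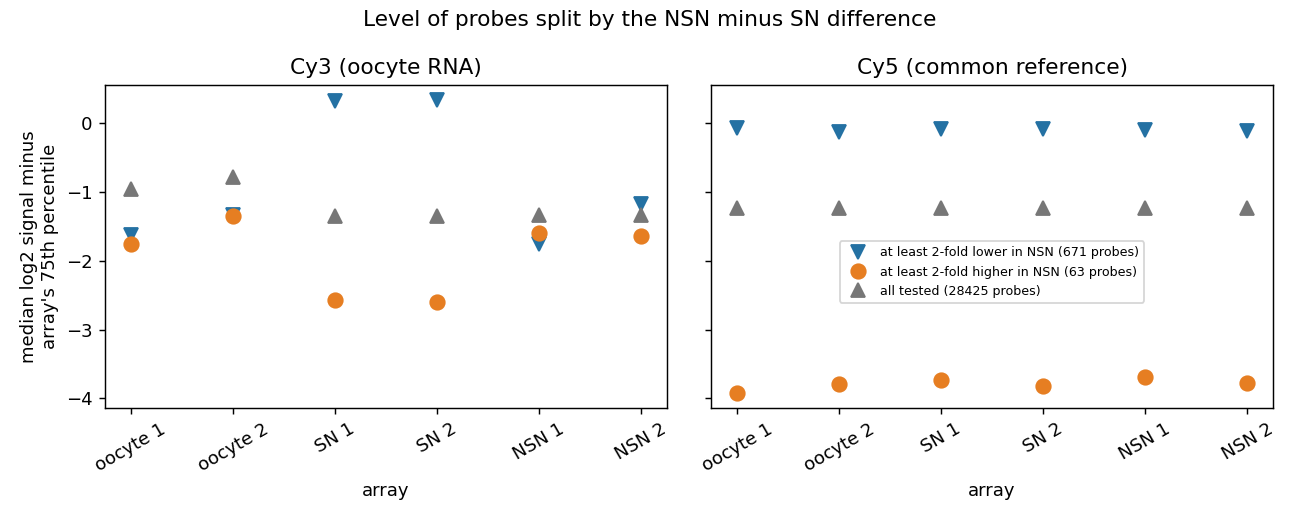
Median log2 signal of 3 sets of probes on each array, relative to the array's 75th percentile, in the Cy3 channel with the oocyte RNA and in the Cy5 channel with the common reference. The 671 probes lower in NSN lie at 0.31 and 0.34 on the SN arrays and between -1.75 and -1.17 on the other 4 in Cy3, while in Cy5 they stay between -0.13 and -0.076 on all 6 arrays.

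SN oocytes differed from the group labelled oocyte over most of the array. limma called 17914 of 29046 tested probes, 61.67 percent, with 7651 higher and 10263 lower in SN. Of these, 5610 were at least 2-fold higher and 6873 at least 2-fold lower, and the far end lay on the higher side, with 543 probes at least 16-fold higher and 66 at least 16-fold lower. Detection was one-sided as well: 3658 probes were well above background on both SN arrays and on neither oocyte array, and 165 the reverse. Probe Z00052106-1 (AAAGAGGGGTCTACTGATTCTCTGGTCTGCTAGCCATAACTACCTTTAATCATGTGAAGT) was higher in SN, where its log2 ratio was 7.87 ± 0.072 (SD, n = 2), than in oocyte, where it measured -0.25 ± 0.18 and was not well above background (limma, adjusted p = 1.58e-05). Its difference ranged from 7.11 to 11.43 over the settings run, so no fold is given. Probe Z00031341-1 (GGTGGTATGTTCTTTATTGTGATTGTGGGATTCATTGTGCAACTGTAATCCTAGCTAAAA) rose by 7.83 (SE 0.18, limma adjusted p = 1.58e-05), from 1.51 ± 0.30 in oocyte to 9.34 ± 0.051 in SN, and the difference lay between 6.29 and 8.04 over the settings run. In the other direction, Z00024684-1 (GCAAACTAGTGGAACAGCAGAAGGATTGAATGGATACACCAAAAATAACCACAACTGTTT) fell by 7.83 (SE 0.22, limma adjusted p = 1.58e-05), from 8.12 ± 0.073 in oocyte to 0.29 ± 0.19 in SN, with a difference between -9.19 and -6.02 over the settings run. Probe Z00063266-1 (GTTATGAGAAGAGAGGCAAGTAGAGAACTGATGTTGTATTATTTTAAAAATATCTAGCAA) fell by 6.93 (SE 0.25, limma adjusted p = 1.72e-05) and was well above background on 1 of the 2 SN arrays, so the size of its fall is uncertain; over the settings run the difference lay between -8.89 and -4.35. The balance of directions depended on the normalisation: with median centring in place of loess, which moved the median difference of all probes from -0.09 to 0.45, 84.3 percent of the called probes were higher in SN, against 42.7 percent with loess. Each oocyte array lay on a slide of its own and held fewer oocytes, so pool size and preparation cannot be told apart from the group here. Slide and scan differed as well; in the Cy5 reference of the same arrays the SN minus oocyte differences had an SD over probes of 0.36 and 4442 calls, against 1.77 and 24950 in Cy3, each channel scaled alone. The count for Cy3 alone depended on the scaling. It was 18313 with the processed signal scaled to the 75th percentile and 17510 with quantile normalisation. In the fit of log ratios with slide as a random block, 17518 probes were called.

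NSN oocytes also differed from the oocyte group over most of the array. limma called 17625 of 29047 probes, 60.68 percent, with 7383 higher and 10242 lower in NSN. At least 16-fold differences again lay mostly on the higher side, 462 probes against 35. Probe Z00052106-1 was higher in NSN too, at a log2 ratio of 7.85 ± 0.13 (SD, n = 2) against -0.25 ± 0.18 in oocyte, where it was not well above background (limma, adjusted p = 1.9e-05), with a difference of 6.98 to 11.55 over the settings run. Probe Z00048212-1 (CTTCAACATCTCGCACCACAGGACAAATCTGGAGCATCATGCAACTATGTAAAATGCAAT) measured 7.67 ± 0.073 in NSN and -0.094 ± 0.012 in oocyte, where it was not well above background (limma, adjusted p = 1.9e-05). Its difference ranged from 6.74 to 12.54 over the settings run. Probe Z00024684-1 fell by 7.95 (SE 0.22, limma adjusted p = 1.9e-05), with a difference between -9.29 and -6.23 over the settings run. Probe Z00063266-1 fell by 6.59 (SE 0.25, limma adjusted p = 2.19e-05) and was well above background on 1 of the 2 NSN arrays; its difference lay between -8.35 and -4.17 over the settings run. Both comparisons use the same oocyte arrays and therefore share their chance departures. With median centring 82.1 percent of the called probes were higher in NSN, against 41.9 percent with loess. With slide as a random block, 17223 probes were called.

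**Figure D3:**
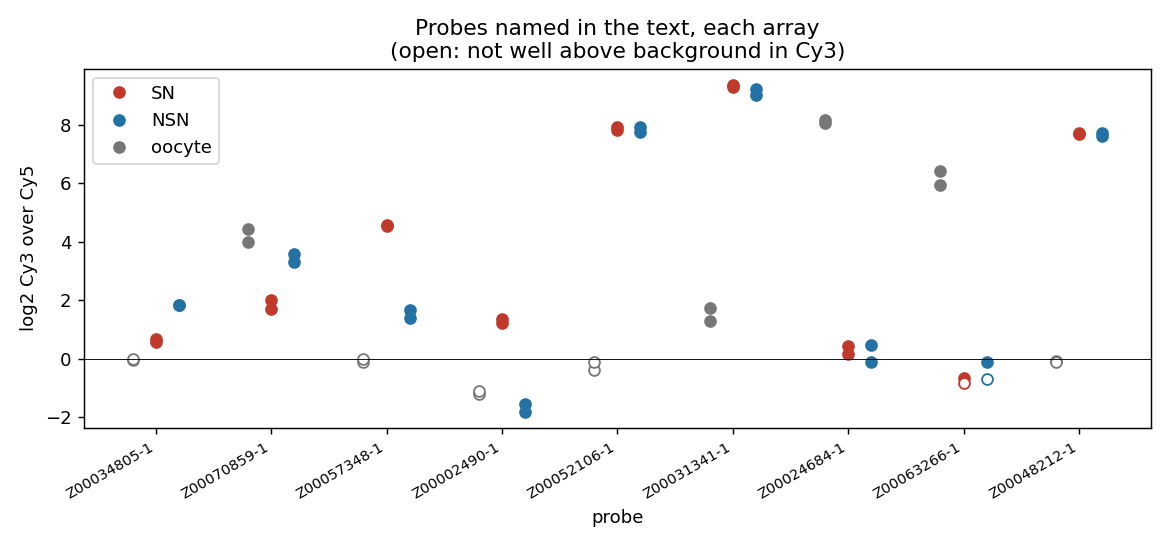
Log2 ratio of Cy3 over Cy5 on each of the 6 arrays for the 9 probes named here, with 2 points per group; open circles were not well above background in Cy3. For Z00057348-1 the SN arrays stand at 4.55 and 4.56 and the NSN arrays at 1.40 and 1.66, while for Z00052106-1 the SN and NSN arrays lie between 7.76 and 7.95.

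NSN profiles lay closer to the oocyte group than SN profiles did. The log ratios of NSN and oocyte arrays correlated across probes with r from 0.7732 to 0.798, and those of SN and oocyte arrays from 0.7543 to 0.7681. For each oocyte array, both NSN arrays correlated more than both SN arrays, and the mean difference in r was 0.0239. With 2 arrays per group the smallest p that regrouping the 4 arrays allows is above 0.05, so this difference was not tested.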

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

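The quality-control probe eQC-39, a control spot that entered no comparison, gave signal in the oocyte channel: on average 95 percent of its 10 spots were well above background in Cy3 on the SN and NSN arrays, against 0 percent on both oocyte arrays and at most 1.31 percent of the 153 negative control spots on any array. Its median log2 processed Cy3 signal was 7.2 and 6.53 on the SN arrays and 5.8 and 5.56 on the NSN arrays, and in the reference channel all its spots were well above background on all 6 arrays.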

How the results depend on the processing

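The counts of probes 2-fold apart and the settings run on them were chosen after the data were seen; all other settings were fixed before. Between NSN and SN, limma called 0 probes under each setting run except median centring (135) and all 6 arrays in one fit (89). For the 63 probes at least 2-fold higher in NSN, the count was 213 with offset 16, 633 with the deposited log ratio, 602 and 3 with Cy3 alone (75th percentile and quantile), 4 with median centring, 119 with the other scan, 37 with probes well above background in both channels on all arrays, 155 with the authors' processed values, and 124 to 287 with 1 array left out. For the 671 probes at least 2-fold lower, it was 1538 with the deposited log ratio and 1667 with Cy3 alone (75th percentile), and 582 to 1000 with 1 array left out. The lower count exceeded the higher one in each of these settings, and 440 to 671 of the 671 probes were again among the lower ones. Of the 63 higher probes, 2 to 63 recurred. The count was 2 with Cy3 alone (quantile), 4 with median centring and 33 with the authors' processed values. With 1 array left out non-overlap is easier to meet, so those counts do not compare directly with the main ones. The cause of the other shifts was not tested. Calls against oocyte fell to 11430 (SN) and 11193 (NSN) with the authors' processed values, which hold fewer probes, and ranged from 15811 to 17585 and from 15290 to 17399 with 1 array left out; a group left with 1 array is assumed to vary like the others. Replicate numbers were not taken to pair the pools in the main fit. Same-numbered deviations correlated at 0.207 between SN and NSN and at -0.0225 and 0.149 with oocyte. An effect shared by same-numbered SN and NSN arrays is not excluded. Replicate 1 against replicate 2 gave 265 probes 2-fold apart without overlap, against 92 with the numbers crossed. A replicate block moved the NSN against SN probes with an unadjusted limma p under 0.05 from 3107 to 3854. With the replicate block 0, 18146 and 17877 probes were called. Cy3 alone (75th percentile) moved the median SN minus oocyte difference to -0.33. Of the named probes, no difference changed sign; 5 values of NSN against SN passed the threshold. Using all probes in place of 1 per gene is the setting reported, and the gene lists and their alternatives were not run, because the probes carry no gene names. Signal over background limits the comparisons with oocyte, since its arrays had the fewest probes well above background.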

Other observations

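Of the tests below, those of the NSN and SN tail, the reference channel and the motif checks beyond the first matching were chosen only after the result was seen; the tests on base composition, on probes measured on all arrays, on the closeness of NSN to oocyte and the first motif matching were written before.

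Probes that carry a poly(A) signal hexamer had other medians than the rest, and this difference was not tested. Against oocyte, the 3222 such probes had a median of 0.26 in SN and 0.14 in NSN on the log2 scale, where the other probes had -0.13 and -0.14. Between NSN and SN, 3172 such probes had a median of -0.055 and the others 0.041. The strand was not settled for each probe: the hexamer AATAAA occurred in 2911 probes and its reverse complement TTTATT in 1413. This excess of AATAAA argues against most probes being written as the complement of the mRNA.

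The excess of probes lower in NSN than in SN was weighed against 4 explanations. Regrouping the 4 arrays gives only 3 splits, too few for a share under 0.05; 1 split, the real one, gave 734 probes at least 2-fold apart without overlap, and the highest other gave 265. An effect of array position or hybridisation common to both dyes is argued against by the reference channel. By the same rule it gave 0.887 percent as many probes as Cy3 on the same arrays (7 against 789). The SN arrays lay at positions 1 and 2 of the slide and the NSN arrays at 3 and 4. An effect of position on Cy3 alone therefore cannot be told apart from the class. Noise of dim probes as the whole cause is argued against too. Of the 671 probes, 48.3 percent (exact 95% interval 44.4 to 52.1) lay above the median NSN Cy3 level of all tested probes. Being lower in NSN works against that. The interval treats probes as independent and does not measure the spread between pools. The 324 probes above that level compare with at most 32 of the same kind in the other splits. RNA of other cells in the SN pools cannot be told apart from a difference between the oocytes, because the median reference level of these probes stood at the 56.6th percentile of 10000 lists matched on SN level and no probe could be assigned to a cell type; the chromatin class itself stays open and untested, as does the RNA preparation of each pool.

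The same 671 probes also moved within the NSN group. They were chosen on these same arrays, with both NSN arrays below both SN arrays. An NSN array between SN and the other NSN array follows from that choice, and the size of the gap may in part. Their median was 0.42 higher on the log2 scale in NSN replicate 2 than in replicate 1, above all 10000 matched lists (median -0.0061), while between the SN pools it was 0.0014, slightly below its matched lists (median 0.043, 0.09th percentile). NSN replicate 2 thus stood between SN and NSN replicate 1 for these probes, and without NSN replicate 1 the count of lower probes was 582. A candidate explanation is that NSN pools held different shares of oocytes near the SN state, or of RNA from other cells. Pool size ran in the same order, with 41 oocytes in NSN replicate 1, 44 in NSN replicate 2 and 50 in each SN pool. The oocyte pools, with 10 oocytes each, did not extend this order. Their medians were -1.2 and -0.943, above -1.39 in NSN replicate 1, but they differed in slide and group as well. No test here separates these explanations.

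The wide difference between the oocyte group and the others was weighed against 3 technical explanations. Slide, hybridisation and scan as the whole cause are argued against by the reference channel, for effects common to both dyes. Its SN minus oocyte differences had an SD of 20.6 percent of that in Cy3, although the reference alone also gave 4442 calls. An effect on Cy3 alone is not covered. GC content and a poly(A) hexamer in the probe together explained 1.76 percent of the variance of SN minus oocyte; the distance of a probe from the 3' end was not measured. Lower signal on the oocyte arrays as the whole cause is argued against only for probes measured on all 6 arrays. Of these, 69.42 percent were called, 113 percent of the share among all tested probes (61.67 percent). The rise itself shows little, since such probes are brighter and so easier to call. Probes lost on the oocyte arrays, such as the 3658 well above background on both SN arrays only, are not covered. Amplification from 10 oocytes, the day of preparation, 3' bias and the unstated origin of the oocyte group stay open, since each is confounded with the group.

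The closeness of NSN to oocyte was smaller but kept its order without the probes 2-fold apart between SN and NSN. Without those probes the mean correlation with oocyte was 0.0145 higher in NSN than in SN, against 0.0239 with all probes. Each NSN array stayed above each SN array for the same oocyte array. Taking out probes chosen for this difference brings SN and NSN closer by itself, so how far the closeness rested on them was not measured. The order also held with Cy3 alone (mean difference 0.0139) and with the deposited log ratio (0.0284), and was absent in the reference channel (-0.000121). A biological explanation, that the oocyte pools held more NSN than SN oocytes, was not tested, because the labels do not give their chromatin class. Pool size cannot be told apart from it, since the oocyte pools held 10 oocytes, the NSN pools 41 and 44, and the SN pools 50. Array position cannot be told apart either. The oocyte arrays lay at position 4 of their slides, the NSN arrays at 3 and 4, and the SN arrays at 1 and 2.

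A hypothesis on regulated mRNA was examined with 2 motifs of 3' untranslated regions, searched in the 60 bases of each probe only. Each p-value below compares probes with random lists of probes on the same arrays, so it does not measure the spread between pools. Against oocyte, an effect of pool size, slide or preparation on these probes cannot be told apart from regulated mRNA. Probes with a cytoplasmic polyadenylation element, a signal for tail extension in oocytes, had a median SN minus oocyte difference of -0.216 (1132 probes), against a median of -0.0498 in 2000 lists matched on GC content and level (adjusted p = 0.004 over 4 tests, permutation of lists). It also lay below lists matched on A and T content (-0.0256), and below the matched lists in each of 6 other settings. The reverse complement went the other way and further, at 0.254 against -0.0358 in its matched lists, a departure of 0.29 (p = 0.001 by permutation of lists). A departure of the element's size is therefore not particular to the element. The reverse complement resembles the poly(A) signal, so the position of the probe may play a part. Between NSN and SN the motif gave -0.0255 against -0.0048 (adjusted p = 0.032), and it lay outside lists matched on A and T content too (median 0.0019, p = 0.002 by permutation of lists). The reverse complement gave as large a shift (-0.0284), and against the lists of GC content and level p was 0.184 with median centring and 0.068 with the authors' processed values, so an effect of the motif stays open there. The AU-rich element, a decay signal, lay inside the matched range in both comparisons. For NSN minus SN its median was -0.00583 against 0.0027 in the matched lists (285 probes). For SN minus oocyte it was -0.224 against -0.0649 (292 probes), a departure of -0.159 about as large as that of the polyadenylation element (-0.166), so fewer probes and not a smaller shift set these results apart.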
